A study of Mus musculus with 6 samples.

How the data were processed

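Gene expression was measured with Affymetrix mouse arrays in aortic roots of klotho-deficient mice, homozygous for a mutant klotho allele, and of wild-type mice. Per the labels, the dissected root held valve leaflets, annulus and part of the ascending aortic wall, and the mice were 6 to 6.5 weeks old on an albino C57BL/6J background. Each of the 6 arrays carried RNA pooled from 3 mice, with 3 arrays and so 9 mice per genotype. RNA was extracted with Trizol, amplified with a NuGEN WT-Ovation Pico kit and labelled with biotin, per the labels' protocols. The pools are the replicates, so p-values reflect the spread between pools of mice and not between single mice.

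The deposited values were linear array intensities, 1 per probe set for 45101 probe sets, from 0.1 to 131884.9 with no value at 0. RMA is the tool in the submitters' processing notes, with no version; RMA commonly returns log2 values, and the step that gave this linear scale is not given in the sources used here. The mean after trimming 2% at each end was 1499.6 to 1499.7 on every array, so the deposited intensities had been scaled to a common mean. Medians were 425.6 to 556.6, so the arrays did not share 1 distribution. Whether RMA gave the deposited values is therefore not known here. No genome build is given in the sources used here and no coordinates are printed.

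Values were log2-transformed with no pseudocount and no further normalization. Low intensities have no floor, so folds of dim genes are unstable. No detection calls were used; background was described by 27 Bacillus control probe sets, which match no mouse transcript, with a median signal of 26.35 and a highest signal of 161.8. A gene was called below background in a genotype when none of its probe sets exceeded that highest signal there on any array, and its fold was then given only as a lower bound against that level. The share of probe sets above it was 69% to 75.4% per array. The number of arrays limits the precision.

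The platform annotation gave 1 gene to 34945 probe sets, several genes to 932 and none to 9160; 64 were controls. Through the RefSeq table of GRCm38.p6, 34741 probe sets had their gene identifier found and 0 symbols changed. Each gene was represented by the probe set with the highest mean log2 intensity, which gave 18193 genes. Of these, 13322 (73.2%) had a mean above the highest Bacillus control.

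Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), with 4 residual and 2.1 prior degrees of freedom. Before the data were examined, 50 gene lists for pathways and cell types of this tissue were fixed and tested with limma's camera at its preset correlation of 0.01. Camera was repeated with an estimated correlation. Limma's fry tested whether a list moved one way, or in either direction. Members were also tested with the adjustment over the list alone, which does not correct for the number of lists, 50. Adjusted p-values in the text come from these tools. Differences are klotho-deficient minus wild type on the log2 scale, ± SE from limma; signals are mean ± SD over 3 arrays.

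Named genes followed a rule fixed in advance. It took 11 genes of interest, of which 9 were measured; then up to 12 genes per direction past the threshold or, where fewer passed, those of smallest p, skipping 4 clone names; and the leading members of each list, 4 where camera passed and up to 2 otherwise. Genes named outside this rule are other list members, sex-linked transcripts and genes singled out after their values were seen.

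The procedure was tested on simulated data built from these arrays, with 200 of 18193 genes changed in each of 20 simulations. It recovered 2.1% of genes changed by 1 on the log2 scale, 26% at 1.5, 75.2% at 2.5 and 90.3% at 4, with 117 false calls among 2053. Camera found 97 of 100 lists shifted by 0.6 and called 6 of 900 others. Genes were simulated independently of each other, so these camera rates do not hold for lists whose genes move together across arrays. Alternatives planned in advance were a replicate block, quantile normalization, median centring, filters on dim genes, a trended and robust variance prior, array weights, other summaries of probe sets, a per-gene test with unequal variances, other thresholds, each array left out, and other list tests. Added after the data were seen were an offset of 100, a covariate for arrays without Y-linked transcripts, several settings combined, and both genotypes without replicate 3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.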

Results

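Transcript levels were measured in 6 pools of aortic roots, 3 from klotho-deficient mice and 3 from wild-type mice. Klotho is a co-receptor for the phosphate-regulating hormone FGF23, and mice without it develop early ageing features and soft tissue calcification. The comparison of the 2 genotypes asks which transcripts differ in the valve, annulus and adjoining aorta at 6 to 6.5 weeks. Correlations of log2 signals across the 13322 genes above background were 0.947 to 0.963 among klotho-deficient arrays, 0.964 to 0.98 among wild-type arrays and 0.946 to 0.97 between genotypes; these are across genes, which are not independent replicates. The ratio of 3' to 5' Gapdh control signals, a measure of RNA integrity and amplification, was 7.18 on wild-type replicate 3 and 3.23 to 4.08 on the other arrays. The same ratio for Actb was 1.1 on that array and 1.07 to 1.18 on the others, so it did not set that array apart.

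The targeted gene did not separate the genotypes. Kl (probe set 1451892_at) gave signals of 138.3, 217.4 and 189.1 on the klotho-deficient arrays and of 166.7, 184.7 and 202.1 on the wild-type arrays, close to the highest Bacillus control at 161.8. The difference was -0.04 ± 0.23 (adjusted p = 0.983), and its sign turned without klotho-deficient replicate 1 (0.14) or wild-type replicate 3 (0.02). The other Kl probe set was dimmer, at means of 49.67 and 72.67. Where these probes lie relative to the mutation is not known here, so Kl does not check the labels.

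Genes of the circadian clock differed between the genotypes. Dbp, a clock output transcription factor, was 5.67-fold higher in klotho-deficient roots, at 7598 ± 321 against 1341 ± 66.4 (SD, n = 3). Nr1d2 and Nr1d1, nuclear receptors that repress Arntl, were 2.97-fold and 2.39-fold higher, and the period gene Per3 was 3.23-fold higher (3589 ± 1130 against 1087 ± 238). Arntl, the core activator of the clock also known as Bmal1, was lower, at 696.7 ± 241 against 1423 ± 46.6 (-1.09 ± 0.27). Of 16 measured clock genes, 7 rose (Dbp, Nr1d2, Nr1d1, Per3, Per2, Tef and Cry2) and 2 fell (Arntl and Npas2) in limma when adjusted over the list alone, with adjusted p from 5.97e-05 for Dbp to 0.0436 for Cry2. Over all 18193 genes 0 of them passed, Dbp coming nearest at an adjusted p of 0.0678.

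Clock genes that did not pass over the list alone included Hlf at 0.55 ± 0.26, Nfil3 at -0.51 ± 0.28, Clock at -0.22 ± 0.23 and Cry1 at -0.06 ± 0.18. The list had a median difference of 0.54, with 10 members higher and 6 lower (camera adjusted p = 0.00236), but adjusted p = 0.83 with an estimated correlation. Fry gave an adjusted p of 0.026 for movement one way and 8.6e-05 for change in either direction. All 3 klotho-deficient arrays lay above all 3 wild-type arrays in the list mean, at 0.58 to 0.63 against -0.11 to 0.11. Without klotho-deficient replicate 1, 4 clock genes were higher and 0 lower over the list alone, and the 2 lower calls became 0 without wild-type replicate 2 and 1 without klotho-deficient replicate 2, klotho-deficient replicate 3 or wild-type replicate 1. The labels give no hour of dissection.

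**Figure D1:**
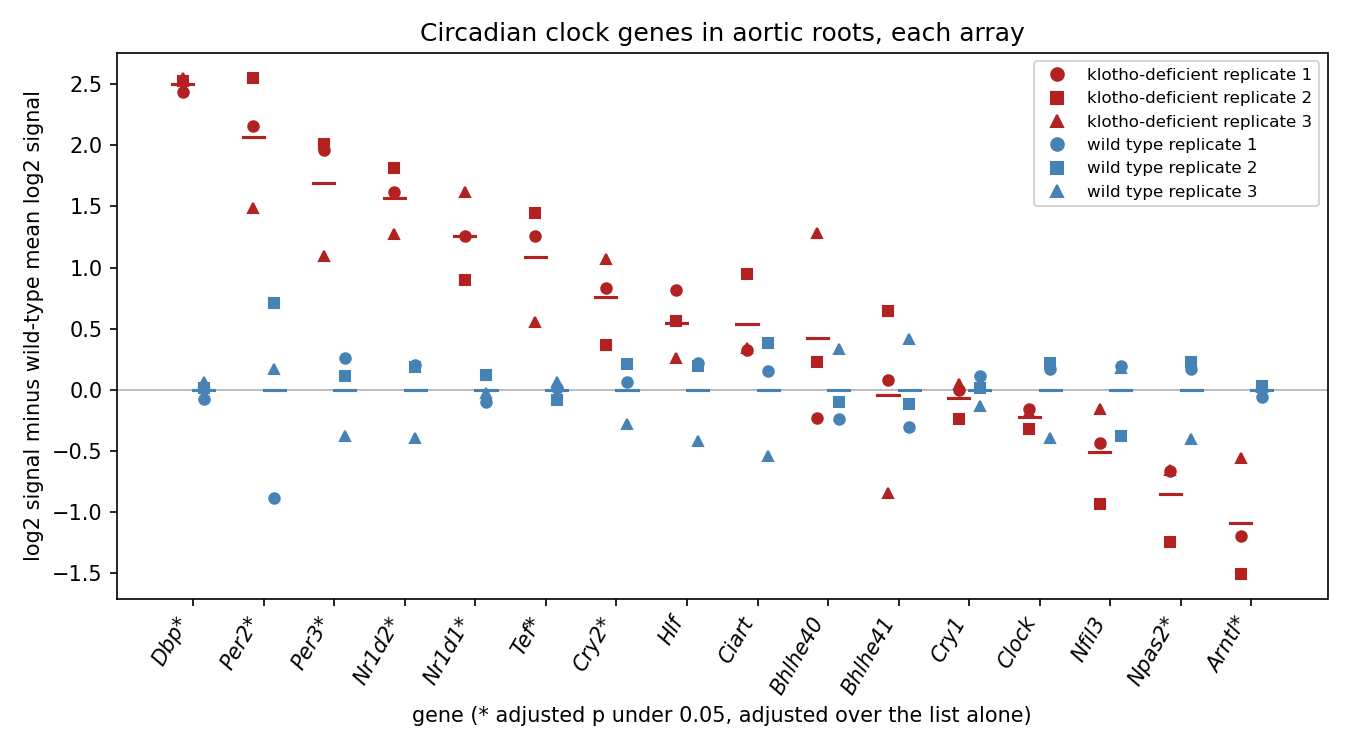
Log2 signal of 16 clock genes on each of the 6 arrays, minus the wild-type mean of that gene; points are arrays, short lines are genotype means, and asterisks mark genes past an adjusted p of 0.05 over the list alone. Dbp, 5.67-fold higher on average, lies far above the wild-type arrays on all 3 klotho-deficient arrays, and Arntl lies below them on all 3.

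Across all 18193 genes, limma called 0 genes higher and 0 lower in klotho-deficient roots. At an unadjusted p under 0.05 there were 591 higher and 575 lower, 1166 in all, where chance gives 910 and another grouping of the same 6 arrays gave 1152. A per-gene test with unequal variances called 1 gene, Dbp. The 2 genotypes did not overlap in 2450 genes (13.5%, against 10% by chance). In simulations of this comparison the test recovered 2.1% of genes changed by 1 on the log2 scale and 75.2% of those changed by 2.5, so smaller differences would mostly be missed. Dbp passed when dim genes were left out (adjusted p = 0.00243); over 22 other settings its adjusted p ran from 4.79e-07 to 0.725.

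The genes of smallest p, none of them past the threshold over all genes, numbered 11 higher and 9 lower. Sphk2, a kinase that makes sphingosine 1-phosphate, measured 5470 ± 1210 in klotho-deficient roots and 1392 ± 166 in wild type (1.96 ± 0.23, adjusted p = 0.29). Its other probe set gave -0.25, so the gene's probe sets disagree. Pde1a, a cyclic nucleotide phosphodiesterase, measured 4683 ± 292 against 2253 ± 108. Zc3h6, Slc1a2, a glutamate transporter, and Fam47e measured 568.8 ± 123, 441.7 ± 57 and 652.3 ± 235 against 157 ± 28.6, 173.4 ± 14.8 and 131.8 ± 38.7. The other Zc3h6 probe set gave 0.12 at a dim signal (112.6 against 100.9). Other Slc1a2 probe sets, dimmer than the one used, ran from -0.64 (20.87 against 29.07) to 1.79 (261.9 against 83.9). In the other direction, Kank4 measured 233.9 ± 47.6 against 818.3 ± 121, Ankrd33b 622.1 ± 23.1 against 1430 ± 199, and Gipc2 242 ± 12.5 against 551.9 ± 74.9.

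The other 11 of these 20 genes were dim. In wild type, Gnrhr and Pcdh17 were below background, and klotho-deficient levels were at least 1.32-fold and 1.10-fold higher. Their other probe sets, all dim, gave -1.21 and 0.20 for Gnrhr and 0.21 for Pcdh17. In klotho-deficient roots, Rnase1, a secreted ribonuclease, and Sftpa1, a lung surfactant protein, were below background and at least 2.11-fold and 1.05-fold lower. Tmco5, Amdhd1, Reg2, Mgat4e, Cpa5, Atp6v1c2 and Cypt4 were below background in both genotypes.

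Ptgs2, which encodes the inducible cyclooxygenase of prostaglandin synthesis, had a mean signal of 6951 ± 3050 in klotho-deficient roots and 1523 ± 464 in wild type. Its difference of 2.11 ± 0.45 did not pass (adjusted p = 0.67), although the arrays did not overlap and its other probe set gave 1.86. The klotho-deficient arrays were 3428.9, 8789.7 and 8634.9, the lowest being replicate 1. Igf1, a growth factor downstream of growth hormone, measured 6457 ± 826 against 9225 ± 893 (-0.52 ± 0.19, adjusted p = 0.755), also without overlap. The prostaglandin list, with 18 measured genes, had a median of 0.01 and 0 genes past the threshold over the list alone; Hpgds, a prostaglandin D synthase, measured 1192 ± 349 against 675.1 ± 99.8.

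The other genes chosen in advance overlapped between genotypes. Sox9, the main chondrogenic transcription factor, was 0.93 ± 0.46, with 2269 ± 1200 against 1116 ± 338. Alpl, the alkaline phosphatase of mineralising cells, was 0.41 ± 0.32, and Cyp24a1, which degrades active vitamin D, was -0.14 ± 0.35. Acta2, smooth muscle actin, was -0.01 ± 0.20, and the cell cycle inhibitors Cdkn1a and Cdkn2a were -0.35 ± 0.38 and 0.31 ± 0.61, the latter with means of 159.8 and 119.7, below the highest Bacillus control. None of the 9 measured genes passed over all genes. The signs for Acta2, Cyp24a1 and Cdkn2a turned under some other settings.

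**Figure D2:**
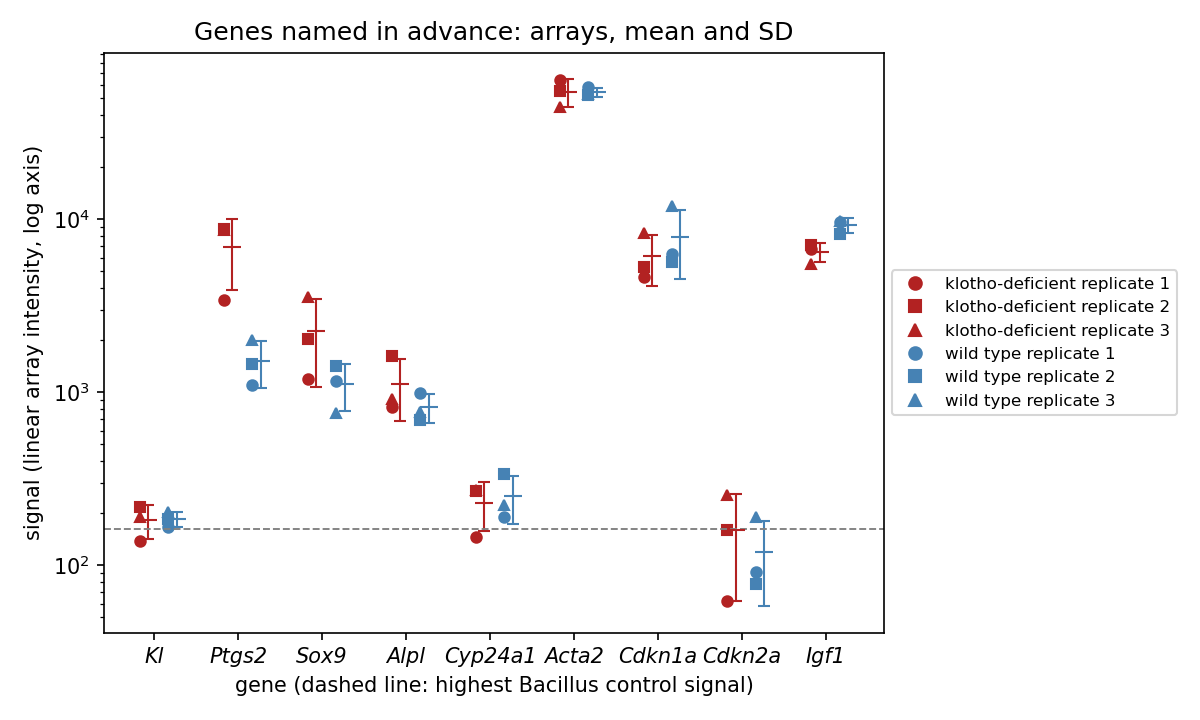
Signal (linear intensity on a log axis) of the 9 measured genes named in advance, with 1 point per array and the mean ± SD beside it; the dashed line is the highest Bacillus control signal, 161.8. Ptgs2 and Igf1 are the genes whose genotypes do not overlap, and Kl lies near the control level in both.

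Genes that respond to glucocorticoids and metals were higher as a list in klotho-deficient roots. Zbtb16, a zinc finger transcription factor, rose 2.77-fold, from 2716 ± 808 to 7381 ± 1080 (adjusted p = 0.0208 over the list alone). The metallothioneins Mt2 and Mt1, which bind zinc, measured 13100 ± 3230 against 4352 ± 2740 and 13860 ± 1730 against 6114 ± 3710, and Lcn2, an iron-siderophore binding protein, 1063 ± 679 against 207.9 ± 88.1. Per1, a period gene that was fixed in this list and not in the clock list, measured 3276 ± 557 against 1525 ± 827. Of 15 measured genes, 13 were higher and 2 lower, the median was 0.34 and only Zbtb16 passed over the list alone. Camera gave an adjusted p of 0.000493, and adjusted p = 0.964 with an estimated correlation. Wild-type replicate 3 stood apart, with a list mean of 0.51 against -0.29 and -0.22 on the other wild-type arrays and Fkbp5, a glucocorticoid-induced chaperone, at 5267.4 against 1017.2 and 1335.6; the klotho-deficient list means were 0.63, 0.51 and 0.88. Without that array the camera adjusted p was 1.47e-09.

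Endothelial genes were lower as a list. Tek, the angiopoietin receptor of endothelial cells, measured 5924 ± 365 against 9235 ± 1730 (-0.63 ± 0.20), Icam2, an endothelial adhesion molecule, 1059 ± 80.9 against 1957 ± 826, Mmrn2 1282 ± 350 against 2227 ± 662 and Tie1 591.5 ± 17.1 against 814.8 ± 191. Of 20 measured genes, 17 were lower and 3 higher and 0 passed over the list alone, with a median of -0.27. Camera gave an adjusted p of 0.00845, and adjusted p = 0.964 with an estimated correlation. The list mean of wild-type replicate 3 was 0.44, and those of wild-type replicates 1 and 2 were -0.30 and -0.14, within the klotho-deficient range of -0.46 to -0.13. The adjusted p was 0.522 without that array and 0.148 without klotho-deficient replicate 2. Epithelial and mesothelial markers went the same way, 11 of 14 being lower with a median of -0.56 (adjusted p = 0.0954, and 0.964 with an estimated correlation), and were also highest on wild-type replicate 3, as with Krt19 at 4739.8 there and 2693.4 to 2954.3 on the other wild-type arrays.

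Clock, glucocorticoid and endothelial genes were the 3 of 50 lists past the threshold in camera, and 0 lists passed with an estimated correlation. In 11 lists the median, the mean and the camera direction did not share a sign, and 0 of those passed.

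**Figure D3:**
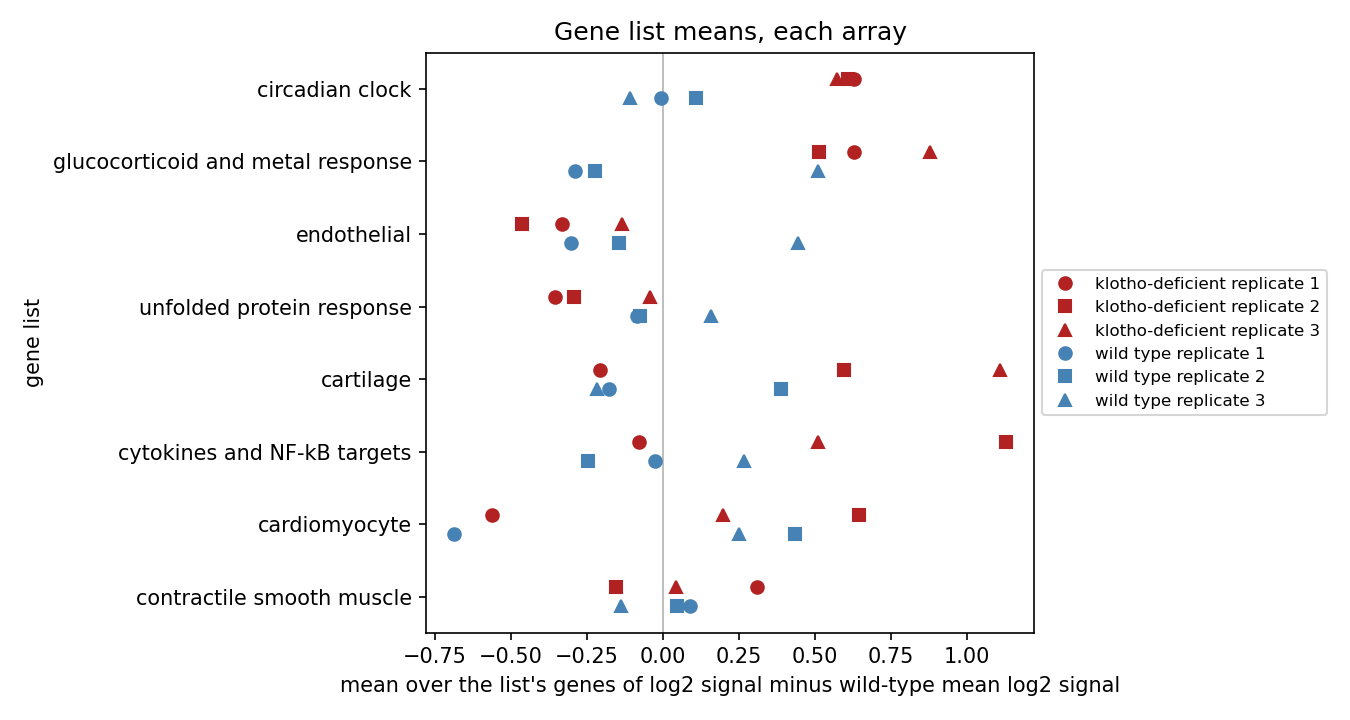
Mean over each list's genes of log2 signal minus the wild-type mean, per array, for 8 lists; each point is 1 array. Clock means separate the genotypes, whereas the endothelial and glucocorticoid means of wild-type replicate 3 lie apart from the other wild-type arrays, and cartilage is highest on klotho-deficient replicates 2 and 3 (0.60 and 1.11).

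Skeletal and mineralisation genes gave few calls. Dcstamp, needed for fusion of osteoclasts, rose to 446.3 ± 85.9 in klotho-deficient roots and was below background in wild type, at least 2.73-fold higher; among 11 osteoclast genes it was the 1 past the threshold over the list alone. Cartilage genes had a median of 0.36, with 20 of 28 higher (camera adjusted p = 0.0653); Cnmd, chondromodulin, measured 733.2 ± 361 against 274.1 ± 86.6 and Prg4, lubricin, 10580 ± 6750 against 3381 ± 687. Klotho-deficient replicate 1 had a cartilage mean of -0.21, within the wild-type arrays' range of -0.22 to 0.39. The list passed in camera without that array (adjusted p = 2.61e-06) or without wild-type replicate 2 (0.00413). With all arrays and an estimated correlation the cartilage list did not pass, as none of the 50 lists did. Among 15 osteogenic genes 0 passed. Sost, the Wnt inhibitor sclerostin, measured 2116 ± 592 against 3889 ± 763 and Smpd3, a sphingomyelinase active in bone, 654 ± 52.3 against 1023 ± 163. Other Smpd3 probe sets gave -0.14 (230.2 against 253.8) and, at a dim signal, -2.04 (32.7 against 157.5). Lists for calcification inhibitors and phosphate handling, vitamin D response, and the klotho and FGF23 axis had camera adjusted p of 0.834, 0.876 and 0.655, with 0 members past the threshold.

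Matrix, valve and smooth muscle lists did not pass in camera. Timp1 and Timp4, inhibitors of matrix metalloproteinases, measured 7093 ± 3950 against 1787 ± 210 and 2891 ± 979 against 1171 ± 215 (1.77 ± 0.54 and 1.25 ± 0.33, neither past the threshold). Timp1 was 2543.9, 9642.4 and 9093.3 on klotho-deficient replicates 1, 2 and 3, so its mean rests mostly on replicates 2 and 3. P4ha1, a collagen prolyl hydroxylase, measured 1938 ± 57.8 against 3185 ± 330, and the collagen chaperone Serpinh1 24240 ± 1330 against 32970 ± 979. The Notch ligand Dll1 measured 1880 ± 488 against 4279 ± 680 and Wnt9b 525.8 ± 85.8 against 1243 ± 342. The other Wnt9b probe set differed less, at 246.6 against 296.9 (-0.26 ± 0.19). Adjusted p for fibrillar and other collagens, elastic fibre and proteoglycan matrix, valve interstitial genes and contractile smooth muscle were 0.76, 0.9, 0.81 and 0.81. Reln, a glycoprotein of lymphatic endothelium, rose from 656.9 ± 55 to 1250 ± 143 over its list of 7 measured genes alone.

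Inflammatory genes did not pass as lists in camera or singly over all genes. Il6 was below background in wild type and measured 74.3, 808.3 and 56.4 on the klotho-deficient arrays, so its mean rests on replicate 2. S100a9, a subunit of the neutrophil protein calprotectin, measured 859.9 ± 255 against 119.5 ± 163, with 26.3, 24.2 and 307.9 on the wild-type arrays, so the wild-type mean rests on replicate 3. Its partner S100a8 measured 363.2 ± 14.1 against 232.1 ± 1.31, and Lgals3, a macrophage lectin, 3261 ± 1240 against 1310 ± 355; none passed over all genes. The cytokine list, with 17 of 25 genes higher, had a camera adjusted p of 0.154, and interferon response, antigen presentation, and macrophage and monocyte genes had 0.915, 0.789 and 0.449. T cell and thymus genes had a median of -0.37 (adjusted p = 0.106), with Thy1 at 2955 ± 871 against 4829 ± 627.

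Protein-folding genes included Creld2, an endoplasmic reticulum stress gene, which fell from 7717 ± 1840 to 3138 ± 450 (adjusted p = 0.0234 over the list alone). Of 15 genes of the unfolded protein response 13 were lower (median -0.13, camera adjusted p = 0.0528), among them Hspa5, the chaperone BiP, at 20150 ± 1100 against 26470 ± 731. Hsph1, a cytosolic heat shock protein, measured 8032 ± 1190 against 16660 ± 3640. Gclc, which makes glutathione, measured 2979 ± 470 against 1827 ± 130. Lists for oxidative phosphorylation, fatty acid oxidation, glycolysis and hypoxia, cell cycle, and senescence and p53 targets had adjusted p of 0.476, 0.476, 0.81, 0.9 and 0.641.

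Markers of neighbouring tissue and of sex differed among arrays of one genotype. Cardiomyocyte genes had a list mean of -0.56 on klotho-deficient replicate 1 and -0.69 on wild-type replicate 1, and of 0.20 to 0.65 on the other 4 arrays; the list gave an adjusted p of 0.9. Within it Tcap, a sarcomeric Z-disc protein, measured 2908 ± 1020 against 991.4 ± 324. The 3 measured Y-linked genes were above background on klotho-deficient replicate 1 and on the 3 wild-type arrays, and on neither of klotho-deficient replicates 2 and 3. Kdm5d, for example, was 2516.3, 16.1 and 5.8 on the klotho-deficient arrays and 2512.1 to 3267.9 in wild type. Xist, transcribed in females, was 19873.8 to 36290.2 on all 6 arrays. The pools of the 2 genotypes thus differed in Y-linked transcripts. Klotho-deficient replicates 2 and 3 had Xist without Y-linked transcripts, as all-female pools would give. The other 4 arrays had both, as pools of both sexes would give. Sex was therefore unbalanced between the genotypes by these transcripts, and differences carried by klotho-deficient replicates 2 and 3 can follow sex as well as genotype. Slc45a2, a melanocyte transporter, measured 412.3 ± 52.2 against 201.7 ± 22.7 and passed over its list of 8 genes alone, but its other probe set measured 194.2 against 180.1 (0.08 ± 0.26), so the gene's probe sets disagree.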

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

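Tests of sex, RNA quality, hour of dissection, single arrays and heart muscle, and the splits for the clock and for the combined settings, were chosen after the results were seen; the splits for gene and list counts were set beforehand.

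Outside the comparisons above, 2 probe sets without a gene name in the annotation stood above background on all arrays and had an unadjusted p under 0.001. Probe set 1442026_at measured 7146 ± 1860 in klotho-deficient and 1717 ± 442 in wild-type roots, a difference of 2.06 ± 0.32. Probe set 1457800_at measured 1276 ± 228 against 375.2 ± 78.9, a difference of 1.77 ± 0.26. Neither passed in limma over all probe sets (adjusted p = 0.572 for each).

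Clock genes made up 9 of the 14 genes past the threshold over their list alone. Of these Dbp, Per2, Per3, Nr1d1, Nr1d2, Tef and Cry2 were higher and Arntl and Npas2 lower. The 14 genes fell in 6 lists, and the lists other than the clock held 1 each. Since the adjustment over a list alone does not correct for the 50 lists, some such single calls can arise by chance. In camera the glucocorticoid and metal list had the smaller adjusted p, 0.000493 against 0.00236 for the clock. RNA quality of wild-type replicate 3 is argued against as the whole cause, since 8 of the clock genes passed over the list alone without it. Sex of the pooled mice stays open. With a covariate for arrays without Y-linked transcripts, the genotype difference rests on klotho-deficient replicate 1 alone. The median difference of the 9 genes, signed by direction, was 1.26 with and without it, and the median standard error went from 0.27 to 0.41. All 9 kept their sign, but none could turn, because these genes did not overlap between genotypes. They were also picked from the same arrays, so the unchanged size does not decide about sex. It shows only that the difference was present on klotho-deficient replicate 1, which had Y-linked transcripts. Hour of dissection stays open. Output and repressor genes had a median of 1.41 and Arntl-arm genes of -0.51, a gap of 1.92. That gap largely restates the calls above, so it does not test the hour. A later or earlier dissection of one genotype could give it, and so could a shifted clock in klotho-deficient mice. These cannot be told apart without recorded times. In the 10 splits of the 6 arrays, 1 gave as many clock genes over the list alone, the real one with 9, and the highest of the others gave 0; with 10 splits no share under 0.05 can be reached.

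Endothelial genes were lower in klotho-deficient roots as a list (camera adjusted p = 0.00845, adjusted p = 0.964 with an estimated correlation), and a candidate explanation is 1 wild-type array. Wild-type replicate 3 had an endothelial mean of 0.44 while the other wild-type arrays, at -0.30 and -0.14, lay among the klotho-deficient ones, and without it the camera adjusted p was 0.522 and the median -0.06. Without klotho-deficient replicate 2 the adjusted p was 0.148, but the median stayed at -0.24, against -0.27 with all arrays. Wild-type replicate 3 also had the highest Gapdh 3' to 5' ratio, 7.18, though not the highest for Actb (1.1, in a range of 1.07 to 1.18). It had wild-type highs of Fkbp5, Mt1 and Mt2, and the highest mean of epithelial and mesothelial genes, 0.44. That list had a median of -0.56. Without a filter on dim genes it passed in camera neither with all arrays (adjusted p = 0.0954) nor without wild-type replicate 3 (0.522). With all arrays and genes under the 30th percentile left out it passed (0.00706). A p that misses the threshold with 2 wild-type arrays does not show that endothelial transcripts were equal, so a smaller loss in klotho-deficient roots stays open.

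Cartilage genes were high on klotho-deficient replicates 2 and 3, with Col2a1, the main cartilage collagen, at 2890.8 and 4225.9 there and 193.2 to 417.6 on the other 4 arrays. These are the 2 arrays without Y-linked transcripts, and klotho-deficient replicate 1 lay 0.599 below the highest wild-type array (-0.599), within the wild-type range, as sex of the pooled mice could produce; a genotype effect that varies between pools could do so too, and these cannot be told apart because no wild-type pool lacks those transcripts. More annulus in the dissection was not tested and stays open. More heart muscle was expected to put the cardiomyocyte means of both arrays above every wild-type array, which was not seen. The lower of the 2 means minus the highest wild-type array was -0.237. That shortfall is within the spread of the wild-type arrays, so heart muscle is not decided either. The cartilage list passed in 8 of 25 settings of the list tests, and not with an estimated correlation.

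Counts of genes past the threshold were 0 for the real split and at most 0 for the others, so 10 of 10 splits gave as many. With 0 in the real split no other outcome was possible, so this count decides nothing. At an unadjusted p under 0.05 the real split gave 1166 genes and the highest other split, which grouped wild-type replicate 1 with klotho-deficient replicates 1 and 2, gave 1152. The 3 lists past camera's threshold compare with up to 12 in other splits, and 9 of the 10 splits gave at least as many, which points to shared array-to-array structure among list members and not only to genotype. With array weights, a trended and robust prior and the 30th percentile filter together, 191 genes passed in the real split, 1 of 10 splits gave as many and the highest other gave 2. With 10 splits no share can fall under 0.05.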

How the results depend on the processing

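The offset of 100, the Y-linked covariate, the combined settings and the removal of both replicates 3 were chosen after seeing the data. Genes called higher numbered 1 without genes under the 30th percentile, 2 without genes under the median, 2 with a trended and robust prior, 1 with array weights, 1 in the per-gene test with unequal variances, 1 at an adjusted p under 0.10 and 1 with the offset. They were Dbp and, where there were 2, Sphk2; a filter tests fewer genes, and otherwise the cause was not tested. The combined settings called 79 higher and 112 lower (7 to 123 in all without 1 array, 2 with equal weights). Leaving out 1 array, genes lower ranged from 0 to 1, the 1 being Y-linked Eif2s3y without klotho-deficient replicate 1 (-5.59, adjusted p = 0.0229). Lists past the camera threshold, 3 as reported, numbered 5 after median centring, 6 with either dim-gene filter, at 0.10 or with the offset, 8 over all probe sets, 7 with the Y-linked covariate, 1 without both replicates 3, 0 with an estimated correlation, 1 by fry, and 3 to 8 without 1 array (8 without klotho-deficient replicate 1, 5 without klotho-deficient replicate 2). Clock genes higher over the list alone, 7 as reported, were 2 with unequal variances, 3 with the Y-linked covariate and 4 to 7 without 1 array; clock genes lower, 2 as reported, were 1 after median centring, 0 with unequal variances or the covariate, 4 with the combined settings and 0 to 2 without 1 array. Same-number correlations of deviations were 0.0245, -0.0188 and 0.0746 for replicates 1, 2 and 3, against -0.0754 to 0.0545 for pairs of unlike number. Replicates 1 and 2 were thus not paired by number, and replicate 3 lay slightly above every unlike pair. On the first principal component, the main axis of variation among arrays (29.2% of variance), klotho-deficient and wild-type replicates 3 lay at 32.7 and 24.6. The other arrays lay at -29.3 to -1.14, so something shared by both replicates 3 is not excluded. With the replicate block 0 genes were called, 6 lists passed, and 6 clock genes were higher and 1 lower. The Kl difference ranged from -0.19 to 0.14 without 1 array, turning at 0.14 and 0.02. Signs also turned in genes far from any threshold. Without 1 array Acta2 ranged from -0.13 to 0.13 (0.04 without wild-type replicate 1), Cyp24a1 from -0.32 to 0.16, Cdkn2a from -0.14 to 0.88 and Hbb-b2 from -0.73 to 0.0194. Acta2 was 0.0518 after quantile normalization, 0.0804 with array weights, 0.0251 averaged over probe sets, 0.24 with the covariate, 0.11 with the combined settings and 0.12 without both replicates 3. Averaging probe sets gave 0.42 for Cyp24a1, -0.0404 for Bub1b and 0.29 for Rps6. The covariate gave -0.83 for Cdkn2a, -0.38 for Bmper, 0.10 for Col4a3, -0.25 for Myh7, 0.038 for Hbb-b2, -0.13 for Insig1 and 0.18 for Eif2s3y, and cardiomyocyte genes passed downward (camera adjusted p = 0.037). Hbb-b2 was 0.0848 with the combined settings and 0.31 without both replicates 3. Among 1036 pairs of list and setting, 115 changed direction uncalled and 48 passed in 1 of the fits only. Dbp stayed at 2.31 to 2.54 in every setting run.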

Other observations

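Tests of body temperature and of the combined settings were chosen after the results were seen. Several genes outside the fixed lists differed without overlap between genotypes, and were picked after their values were seen. Cirbp, a cold-induced RNA-binding protein, measured 8038 ± 3100 in klotho-deficient roots and 3087 ± 392 in wild type (1.32 ± 0.31, adjusted p = 0.67 in limma). Manf, a secreted protein induced by endoplasmic reticulum stress, measured 5889 ± 443 against 10460 ± 2030, in the same direction as Creld2 and Hspa5. Nampt, the main enzyme of NAD salvage, measured 5307 ± 845 against 3381 ± 266, and Sirt1, an NAD-dependent deacetylase, 1535 ± 176 against 884.8 ± 143. None of these passed over all genes in the main fit.

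Fry's test for change in either direction passed for 6 of 50 lists. Besides the clock (adjusted p = 8.6e-05) these were neutrophil and mast cell (0.00275), lymphatic endothelial (0.00275), osteoclast (0.00499), oxidative stress defence (0.00866) and unfolded protein response genes (0.019). Their leading members were S100a8, Reln, Dcstamp, Gclc and Creld2. The test does not compare a list with other genes.

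When arrays were weighted by their agreement with the fit, wild-type replicate 1 had a weight of 2.43 and klotho-deficient replicate 3 of 0.374. With these weights, a trended and robust prior and dim genes left out, the 191 genes called included 5 of the glucocorticoid and metal list, all higher (Zbtb16, Mt1, Mt2, Per1 and Klf9). Of these, Per1 is a period gene that was not in the clock list. The 191 also included 7 clock genes, 5 higher and 2 lower, and Cirbp, Manf, Nampt and Sirt1 (adjusted p = 0.0054, 0.0142, 0.0287 and 0.0395). Ptgs2 and Igf1 were not among them. The count depended on which arrays were in the fit. It was 50 without klotho-deficient replicate 1, of which 15 were shared with the 191. Without replicates 2 and 3 of that genotype it was 11 and 64, with 11 and 54 shared. It was 7, 12 and 123 without wild-type replicates 1, 2 and 3, with 7, 9 and 112 shared.

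A hypothesis from Cirbp and Hsph1 is that klotho-deficient mice had a lower body temperature, which may also act on clock genes. Without Hsph1, which prompted the hypothesis, 15 of 17 measured chaperone targets of the heat shock factor HSF1 were lower, with a median of -0.27 (camera adjusted p = 0.000452, tested as the only list). The adjusted p was 0.127 with an estimated correlation, a condition added after the first value was seen, and 5 of the 10 splits gave an unadjusted p under 0.05 for this list. Body temperature, hour of dissection and a direct effect of genotype therefore cannot be told apart here.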
